A study of Mus musculus with 9 samples.

How the data were processed

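Poly(A)-selected RNA from mouse splenic CD8+ T cells was sequenced in 9 libraries, 5 wild type (WT) and 4 from cells with a knockout of the gene for RIG-I (Rig1 KO). Total RNA was extracted with TRIzol and libraries were built with a NEBNext mRNA kit, per the labels' protocols. How the CD8+ T cells were purified, and whether libraries were prepared or sequenced in batches, was not given in the sources used here. The groups were taken from the sample titles, which number the libraries within each genotype and name no separate animals, so p-values measure only the spread between these samples, which may be technical.

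The deposited values are TPM (reads scaled by gene length and library total), 1 column per library, as named in the file headers. Reads were trimmed with fastp and counted over genes with featureCounts on the mouse build mm39 (GRCm39), per the submitters' processing notes, which give no versions for either tool. The aligner, the annotation release and the gene lengths behind the TPM values were not given in the sources used here. Each library listed 18188 genes whose TPM values summed to 1e+06, and 17934 genes were above 0 in at least 1 library.

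The TPM values kept enough digits to recover the reads behind them. The scale of each library relative to the first was read from the most frequent ratio of low values (at least 219 genes per library), and each gene's rescaled values were then taken as the smallest whole numbers in the same ratios, within a relative tolerance of 2e-12. This succeeded for 100% of genes. A gene whose reads share a common divisor is recovered too low, so the recovered totals are lower bounds. On simulated counts of 12000 genes the procedure recovered 100% of the genes up to such a common divisor, and at least 99.7% of each library total. The recovered totals ran from 15496262 reads in WT 2 to 17893558 in WT 4 (WT 1 16609273, WT 3 16546458, WT 5 15547103, Rig1 KO 1 to 4 17866952, 16184145, 15651121 and 15509876). The gene lengths implied by the reads lay within 1% of the genomic span of the gene, introns included, for 96.6% of 17486 genes, and within 1% of the exon length for 0.829%. A gene with long introns therefore has a low TPM for its reads, and TPM levels are not comparable between genes. Changes of 1 gene between libraries are affected through the scaling of each library, the filter on low TPM and the 1 added before taking logs. Other choices of each were tested. With exon lengths 11484 genes passed the filter, against 10540 with TPM as deposited.

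Gene names, exon lengths and GC content came from a GRCm38 annotation, an older build than the authors', so no coordinates are given and it served only for names, lengths and neighbouring genes. Of the 18188 genes, 17767 had a position in it. The RIG-I gene is listed under its older symbol Ddx58.

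Genes with a TPM of at least 1 in at least 4 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no covariates. All 9 libraries entered the test, which was two-sided with Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. Adjusted p-values of genes in the text are from this test unless another is named. A log2 fold change on this scale is Rig1 KO minus WT and understates the change of low genes. Values are given as mean TPM ± SD over the libraries of a group. Exact permutation tests compared the values of the 9 libraries over all 126 splits into 5 and 4. Changed genes near the RIG-I gene were compared with all other tested genes by Fisher's exact test, in windows of 10, 5 and 20 Mb.

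Fixed before the data were examined were the groups, the tests, the filters, the rule for named genes, the other choices to try and 27 gene lists of pathways and of cell types that a splenic preparation can hold. The lists held 762 symbols, of which 713 were found, 1 of them through a synonym. The 25 lists with at least 5 tested members, apart from the sex-linked genes, were tested with limma's camera (preset correlation 0.01), adjusted over the lists. This test asks whether a list's genes changed more in 1 direction than all other tested genes did. The test was repeated with a correlation estimated for each list. The gamma-delta T cell list had too few tested members and was not tested, and the sex-linked genes were examined per library only.

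The rule named the RIG-I gene, the 10 genes with the largest rise and the 10 with the largest fall among changed genes with a mean TPM of at least 2 and no overlap between the groups, and up to 4 members of each list with the smallest p. Predicted genes and immunoglobulin or T cell receptor variable segments were counted and not named. Every other gene named in the text was chosen after its values were seen. This covers members of counts of 5 or fewer and the further examples in the gene groups.

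Other choices fixed then were pseudocounts of 0.1 and 0.5, no filter or a mean TPM of at least 5, median ratio and quantile scaling, TPM totals without immunoglobulin, haemoglobin and mitochondrial genes, limma without trend, with robust variances (statmod 1.5.0) or with library weights, the replicate number as a block, each library left out, an adjusted p of 0.1 or an absolute log2 fold change of at least 1, limma's fry for the lists, and other windows around the RIG-I gene. Chosen after seeing the data were limma's voom on the recovered reads, recovered reads scaled to equal totals, TPM rebuilt with exon lengths, removal of trends with exon length and GC content (known for 97.9% of tested genes), the mean of the B cell markers as a covariate, the data without WT 4 and WT 5 (the 2 WT libraries highest in B cell markers), an exact permutation test for each list and a list of 9 basophil markers.

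The tests were checked on simulated data with the means, spread and library sizes of the 9 libraries. Over 10477 simulated genes, limma recovered 70.8% of genes changed 1.5-fold, 87.9% of those changed 2-fold and 96.9% of those changed 4-fold, with 11 false among 178 calls. Over 10479 simulated genes, camera called a list raised 1.5-fold and 0 of 100 unchanged lists. The simulated genes varied independently, and far fewer were changed than were called in the real data. The correlations estimated for the real lists ran from 0.0742 (platelet) to 0.940 (B cell). The check therefore does not show how often camera calls unchanged lists whose genes vary together. Reads were recovered and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.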

Results

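Gene expression was measured by poly(A) RNA sequencing in CD8+ T cells, the lymphocytes that kill infected and malignant cells, from mouse spleens. The series compared 5 libraries of WT cells with 4 libraries of Rig1 KO cells. RIG-I is a cytosolic sensor of viral RNA that triggers type I interferon production, and the study's title names it as a brake on the antitumour activity of these cells. The comparison therefore asks which transcripts differ between libraries labelled with the knockout and WT libraries. In units of 1e+06, the libraries held 16.4 ± 0.980 recovered reads in WT (SD, n = 5) and 16.3 ± 1.08 in Rig1 KO (SD, n = 4). Between 15196 and 15631 genes were above 0 in a library. Mitochondrially encoded transcripts made up 20.1 ± 1.30% of TPM in WT and 21.2 ± 0.979% in Rig1 KO. The lengths behind the TPM values include introns, so these percentages are not shares of the reads or of the RNA. The 16 pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom from 4.60 to 20.1), which does not tell separate animals from repeat preparations. Rig1 KO 1 and 2 (4.60) and Rig1 KO 3 and 4 (6.02) lay closer to each other than across these pairs (9.12 to 15.2). WT 5 lay furthest from WT 1, WT 2 and WT 3 (16.9 to 20.1). The tests took every library as a separate sample, and whether such pairs share a source was not tested.

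The transcript of the targeted gene, Ddx58, was lower in every Rig1 KO library than in any WT library. Its level was 65.1 ± 2.0 TPM in WT (SD, n = 5, range 63.2 to 67.4) and 33.3 ± 2.04 TPM in Rig1 KO (SD, n = 4, range 30.6 to 35.2). The Rig1 KO libraries thus retained 51.1% of the WT level. The log2 fold change was -0.95 (SE 0.055, adjusted p = 4.91e-07), and an exact permutation test of the TPM values gave p = 0.00794 (two-sided), the smallest that the 126 splits of the libraries can give. The values sum reads over the whole gene, so they do not show which part of it the remaining transcript carried.

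The Rig1 KO libraries had far lower levels of the transcripts on the T cell receptor activation list than the WT libraries. Cytotoxic, natural killer type and interferon-stimulated transcripts were mostly higher, though the set tests of these 3 lists did not pass with an estimated correlation (adjusted p = 0.631 for each). Limma's fry, which does not compare with other genes, called all 3 (adjusted p = 0.000186, 0.00364 and 0.00296, in that order). So did the exact permutation test of the list means, chosen after seeing the data (adjusted p = 0.0220, 0.0361 and 0.0220). Fosb, a subunit of the AP-1 transcription factor, fell 21.2-fold, from 1577 ± 149 TPM in WT to 74.2 ± 9.89 TPM in Rig1 KO. Tnfaip3, which encodes the NF-κB inhibitor A20, fell 15.7-fold, from 1843 ± 177 to 117 ± 7.44 TPM. Klrg1, a receptor of terminally differentiated effector cells, rose 9.99-fold, from 2.62 ± 2.20 to 26.2 ± 4.88 TPM. Ccr2, a chemokine receptor of monocytes and effector T cells, rose 5.23-fold, from 21.4 ± 8.07 to 112 ± 13.9 TPM.

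Of 10540 genes tested, 4817 changed (45.7%), 3526 of them higher and 1291 lower in Rig1 KO. The groups did not overlap for 4014 genes (38.1%), against 1.59% by chance. The small changes depended on how libraries were scaled. The median log2 fold change of all tested genes was 0.13 with TPM as deposited and 0.00 after median ratio scaling, under which 2381 genes were higher and 2384 lower. Shifts of a gene or list near this size therefore carry no fixed direction. Among genes with an absolute log2 fold change of at least 1, 250 were higher and 289 lower. The transcripts of B cells were higher and more variable in WT, as described with the other cell types. Without WT 4 and WT 5, the 2 WT libraries highest in B cell markers, 4657 genes changed (3643 higher and 1014 lower), and with the B cell marker mean as a covariate 2765 changed.

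**Figure D1:**
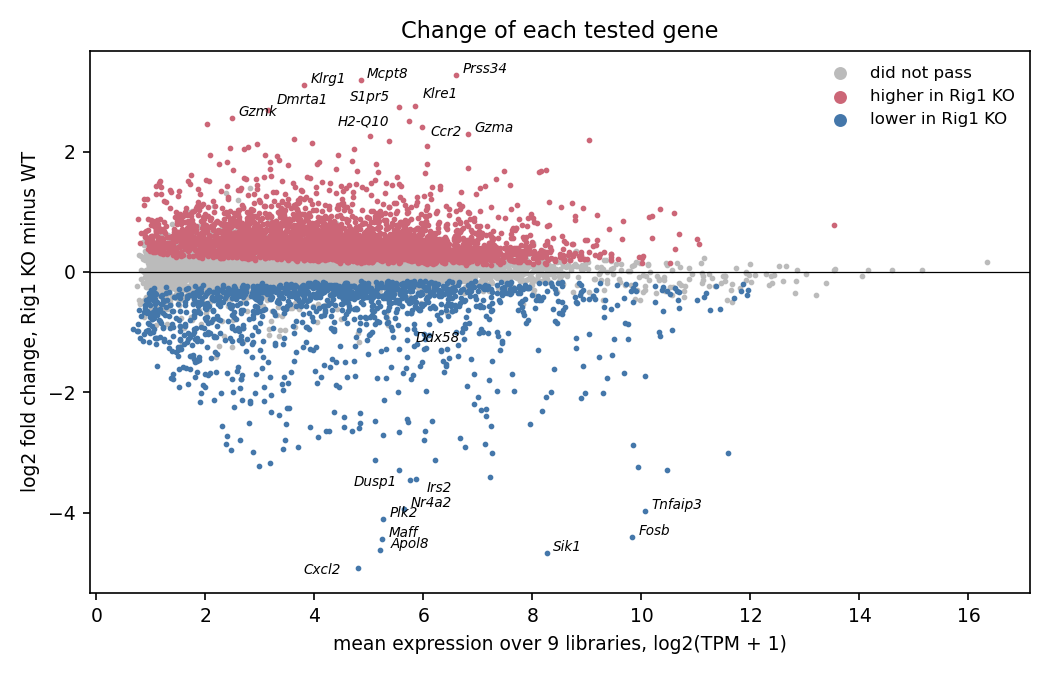
Each point is 1 of the 10540 tested genes. The x axis is log2(mean TPM + 1), with the mean taken over the 9 libraries, and the y axis is the log2 fold change, Rig1 KO minus WT. Genes that passed are red (3526 higher in Rig1 KO) or blue (1291 lower), a split that became 2381 higher and 2384 lower after median ratio scaling. The named genes are Ddx58 and the 10 with the largest rise and the largest fall.

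The 10 genes with the largest rise included the mast cell and basophil proteases Prss34 (21.1 ± 11.8 TPM in WT and 189 ± 68.5 TPM in Rig1 KO) and Mcpt8 (5.10 ± 1.22 and 56.2 ± 22.6 TPM). Granzyme genes, which encode proteases of cytotoxic granules, were also among them, with Gzmk at 0.792 ± 0.475 TPM in WT and 9.41 ± 2.27 TPM in Rig1 KO and Gzma at 46.9 ± 31.7 and 193 ± 47.7 TPM. The lectin-like receptor gene Klre1 rose by 2.76 on the log2 scale and S1pr5, which encodes a sphingosine-1-phosphate receptor that guides lymphocytes out of tissues, by 2.74. Dmrta1 rose by 2.69 and H2-Q10, a nonclassical MHC class I gene, by 2.51. Klre1, H2-Q10 and the granzymes have close relatives in the genome, so their reads could be divided among copies.

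The 10 genes with the largest fall were led by Cxcl2, a neutrophil-attracting chemokine, at 47.9 ± 14.5 TPM in WT and 0.626 ± 0.587 TPM in Rig1 KO, with 7 recovered reads over the 4 Rig1 KO libraries. Sik1, a kinase gene induced by cAMP and calcium signals, fell 26.5-fold from 534 ± 26.0 to 20.1 ± 2.82 TPM. Maff, a small Maf transcription factor, fell by 4.43 on the log2 scale and the stress-induced kinase gene Plk2 by 4.11. Nr4a2, an orphan nuclear receptor induced by antigen receptor signals, fell by 3.94. Dusp1, a phosphatase that switches off MAP kinases, fell by 3.46 and Irs2, an adaptor of insulin receptor signalling, by 3.44. Apol8 fell by 4.62.

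**Figure D2:**
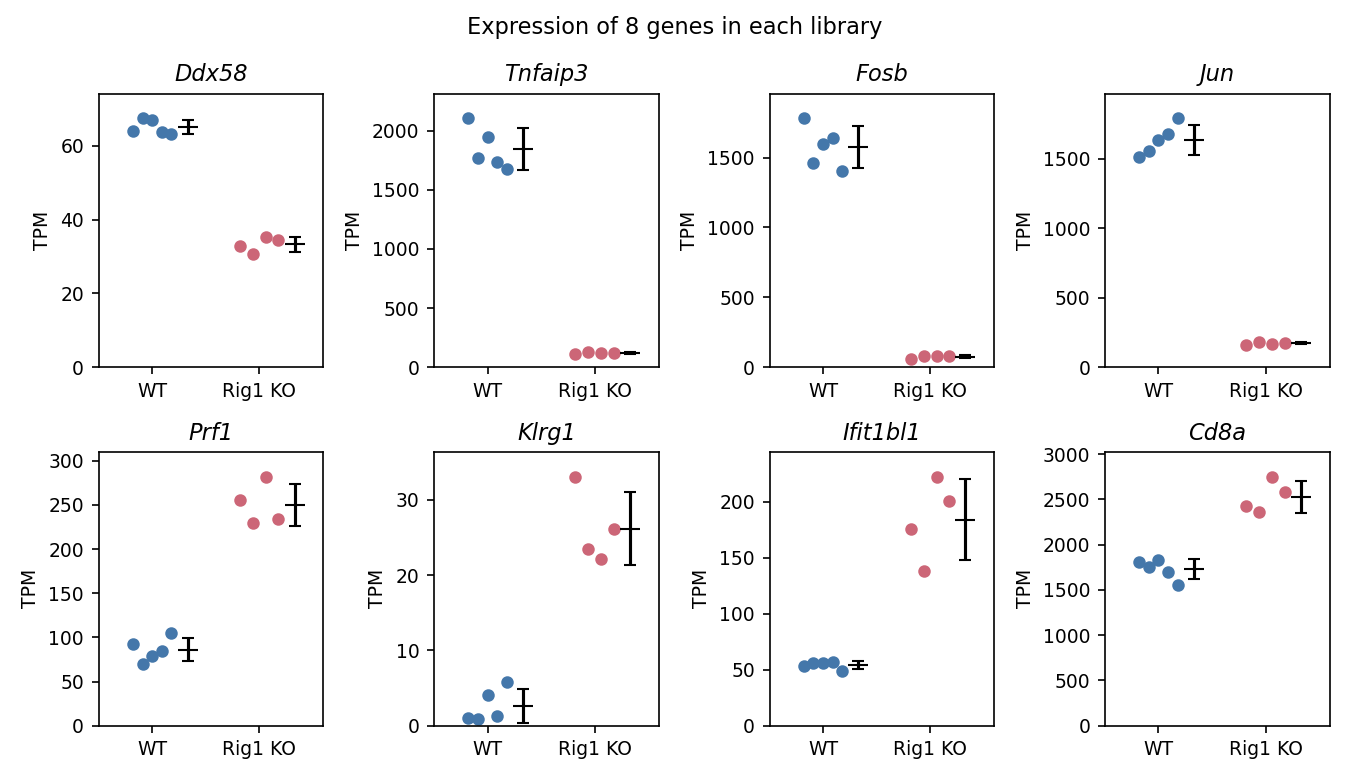
TPM in each library (points, WT n = 5 and Rig1 KO n = 4) with the group mean and SD for 8 genes. Fosb, Tnfaip3 and Jun lay lower in every Rig1 KO library than in any WT library, as did the targeted gene Ddx58, while Prf1, Klrg1, Ifit1bl1 and Cd8a lay higher.

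The listed genes that T cells switch on within hours of antigen receptor signalling were lower in Rig1 KO almost without exception. Receptor signalling itself was not measured and what induced these genes was not tested, so their fall does not show weaker signalling. Of 32 measured members, 29 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone (29 fell, 1 rose). Jun, the partner of Fos in AP-1, fell 9.52-fold from 1634 ± 110.1 to 172 ± 7.81 TPM, and Ppp1r15a, which restarts translation after stress, fell 7.37-fold from 1485 ± 58.5 to 201 ± 16.1 TPM. The activation marker Cd69 fell from 751 ± 90.5 to 186 ± 20.2 TPM. The exceptions were Cd44, an adhesion receptor of experienced T cells, which rose from 17.1 ± 2.67 to 23.1 ± 2.48 TPM, and Ier3 and Irf8, which did not pass (adjusted p = 0.607 and 0.926). The median log2 fold change was -1.67 and the set test gave an adjusted p of 2.98e-32 (0.0134 with an estimated correlation). The counts of 29 lower and 1 higher were the same under median ratio and quantile scaling. With the B cell marker mean as a covariate 24 members fell and 0 rose.

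Cytotoxic effector genes moved the other way. Of 35 measured members, 27 rose, 5 fell and 3 did not pass, and 28 rose and 5 fell adjusted over the list alone. Prf1, the pore-forming protein of cytotoxic granules, rose 2.91-fold from 86.1 ± 13.2 to 250.3 ± 23.7 TPM, and Klrk1, which encodes the activating receptor NKG2D, rose 4.37-fold from 26.4 ± 3.16 to 115 ± 10.5 TPM. Gzmb rose from 96.9 ± 49.8 to 279.5 ± 38.6 TPM and the transcription factor gene Tbx21, which drives effector differentiation, from 22.7 ± 3.50 to 57.2 ± 4.39 TPM. The 5 that fell were Srgn, the granule proteoglycan (136 ± 9.83 to 71.1 ± 3.38 TPM), Ifng (70.2 ± 11.4 to 21.4 ± 5.13 TPM), Bhlhe40, Ifngr1 and Tnf. Serpinb6b, Ccl3 and Ccl4 did not pass. The median log2 fold change was 1.03 and the set test gave an adjusted p of 0.000144, but adjusted p = 0.631 with an estimated correlation. After median ratio scaling 24 rose and 5 fell.

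Markers of natural killer and innate lymphoid cells rose beside the cytotoxic genes. Of 14 measured, 9 rose, 0 fell and 5 did not pass, and 10 rose and 0 fell adjusted over the list alone. Klra9 rose from 3.42 ± 1.35 to 14.0 ± 1.33 TPM and Klrb1c, which encodes NK1.1, from 3.55 ± 1.09 to 9.94 ± 0.987 TPM. Il7r, the interleukin-7 receptor chain that naive and memory T cells also carry, rose from 274 ± 31.2 to 604 ± 63.0 TPM. Ncr1, a receptor largely restricted to natural killer cells, rose from 7.86 ± 5.92 to 25.2 ± 5.22 TPM (adjusted p = 0.00469), while Tyrobp, an abundant adaptor of myeloid and natural killer cells, was at 52.8 ± 21.4 TPM in WT and 62.3 ± 10.7 TPM in Rig1 KO (adjusted p = 0.341). Their median log2 fold change was 0.96, and the set test gave an adjusted p of 0.00701, but adjusted p = 0.631 with an estimated correlation. CD8+ T cells are known to express 8 of the 14 markers, and 2 stand in another of the lists.

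Interferon-stimulated genes were mostly higher in the Rig1 KO libraries. Of 61 measured members, 46 rose, 2 fell and 13 did not pass, and 47 rose and 2 fell adjusted over the list alone. Ifit1bl1 rose 3.41-fold from 53.9 ± 3.45 to 184 ± 36.2 TPM, Slfn1 rose 2.12-fold from 245 ± 12.3 to 518 ± 55.4 TPM, and Usp18, which restrains interferon receptor signalling, rose 3.26-fold from 3.35 ± 0.714 to 10.9 ± 2.35 TPM. The antiviral GTPase genes Iigp1 (17.8 ± 2.85 to 53.7 ± 11.3 TPM) and Mx1 (30.6 ± 4.73 to 71.3 ± 13.4 TPM) rose too. Irf1, which is also induced by interferon-γ and NF-κB, fell from 452 ± 46.6 to 276.5 ± 20.3 TPM, and Ifi27l2a fell from 303 ± 32.2 to 219 ± 26.9 TPM. The median log2 fold change was 0.46, and 37 members rose and 2 fell after median ratio scaling. The set test gave an adjusted p of 1.77e-06, but adjusted p = 0.631 with an estimated correlation. Members of the Ifit, Oas and Slfn families share sequence, so single members among them are uncertain.

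The pathway through which RIG-I signals was not called as a list by camera, while limma's fry, which does not compare with other genes, called it (adjusted p = 0.0212). Of its 31 measured members other than Ddx58, 13 rose, 3 fell and 15 did not pass (13 and 3 adjusted over the list alone), but after median ratio scaling 9 rose and 9 fell. Mavs, the mitochondrial adaptor of RIG-I, rose from 18.8 ± 2.29 to 28.6 ± 2.07 TPM, and Irf3, the transcription factor it activates, from 128 ± 10.3 to 189 ± 5.74 TPM. Sike1, an inhibitor of the kinases in this pathway, rose from 70.9 ± 3.12 to 131 ± 10.1 TPM. Rela and Nfkb1, the NF-κB subunits, and Atg12 fell. This list's median was 0.15, close to the shift of all genes, and the set test gave an adjusted p of 0.591.

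**Figure D3:**
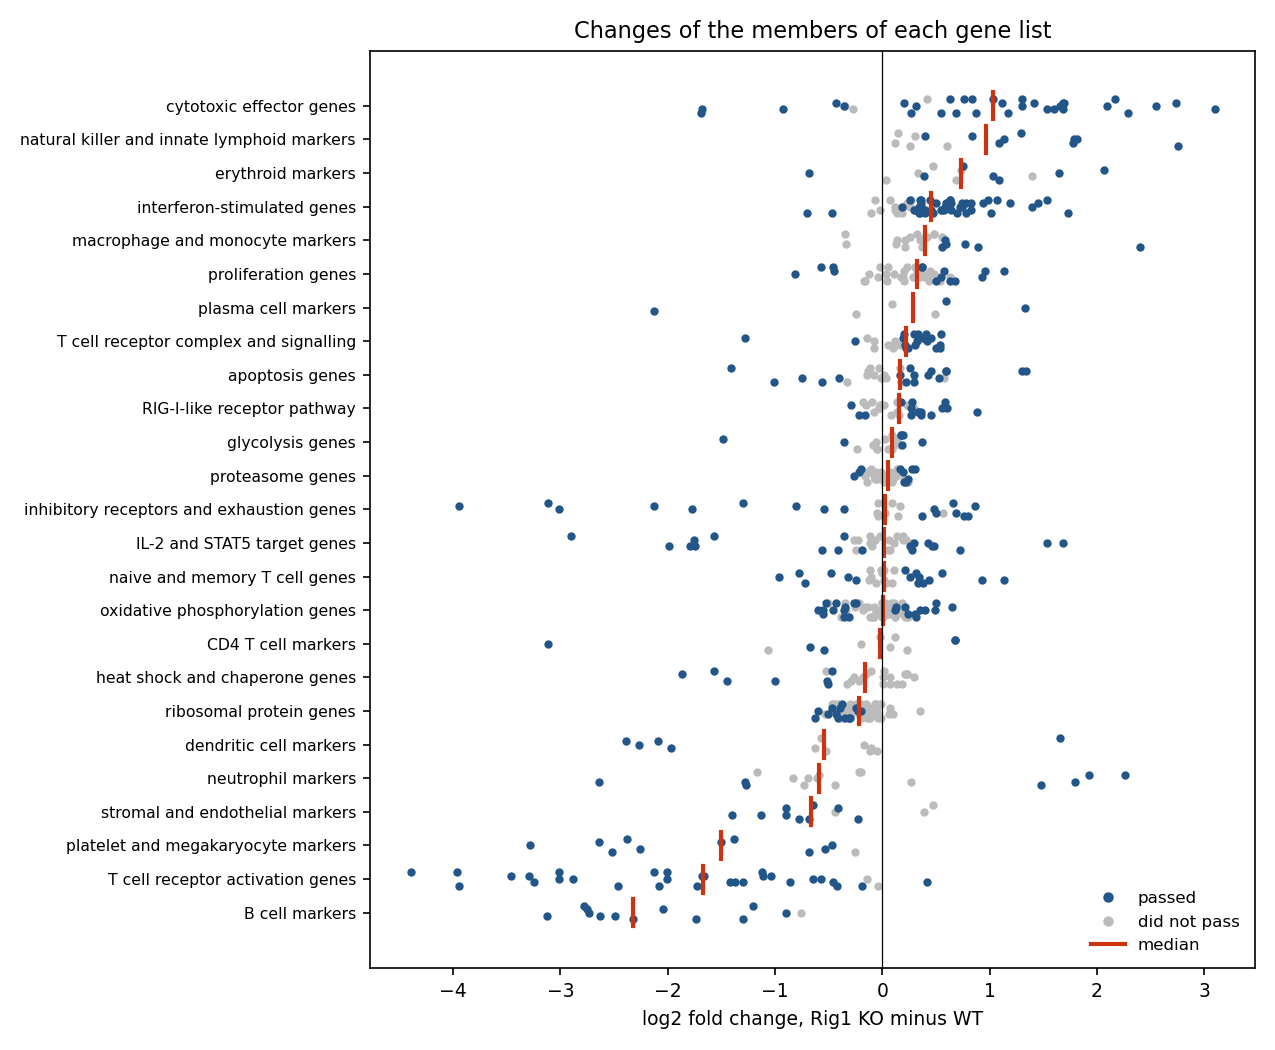
Log2 fold change, Rig1 KO minus WT, of every measured member (points) of the 25 tested gene lists, with the median of each list as a red mark. The medians ran from -2.32 for the B cell markers to 1.03 for the cytotoxic effector genes. The medians of the naive and memory, IL-2 and STAT5, inhibitory receptor, oxidative phosphorylation, glycolysis and proteasome genes changed sign after median ratio scaling. Those medians therefore have no fixed direction. The mean changes of these lists relative to other genes stayed negative under every alternative run, though not all of the lists were called.

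The genes of the T cell receptor complex and its signalling were not called as a list, although the coreceptor genes of CD8+ T cells rose. Of 27 measured genes of the T cell receptor complex and its signalling, 17 rose, 2 fell and 8 did not pass, with 17 and 2 adjusted over the list alone, and 10 rose and 5 fell after median ratio scaling. Cd8a rose from 1731 ± 110.0 to 2528 ± 175 TPM and Cd8b1 from 425 ± 37.8 to 616 ± 19.8 TPM. The costimulatory receptor gene Cd28 fell from 116 ± 15.01 to 47.3 ± 7.51 TPM and Prkcq fell as well. The median was 0.22 and the set test gave an adjusted p of 0.0532, which became 0.0369 without WT 1 and 0.0295 without Rig1 KO 2. It also passed without the filter on low genes (0.00182), after quantile scaling (0.0316) and with totals free of immunoglobulin, haemoglobin and mitochondrial genes (0.0488). It did not pass after median ratio scaling or with an estimated correlation (adjusted p = 0.780), and with the B cell marker mean as a covariate the list's change relative to other genes reversed to -0.0238 (adjusted p = 0.353). The members themselves did not turn downward with that covariate, since 10 rose and 2 fell, with a median of 0.30. Limma's fry, which does not compare with other genes, gave an adjusted p of 0.00597.

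Genes of naive and memory T cells split. Of 27 measured, 10 rose, 6 fell and 11 did not pass (10 and 6 adjusted over the list alone), while 6 rose and 9 fell after median ratio scaling, and 3 rather than 6 fell without Rig1 KO 1 or without Rig1 KO 2. Klf2, which keeps T cells quiescent and is shut off by activation, fell from 1937 ± 154 to 989.6 ± 50.2 TPM, and the lymph node homing receptor gene Ccr7 from 406 ± 13.7 to 290.4 ± 14.8 TPM. Klf3 rose from 136 ± 8.89 to 201 ± 6.44 TPM. The median was 0.02 and the mean 0.05, whereas the set test, which compares with other genes, pointed down with an adjusted p of 0.591.

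The IL-2 and STAT5 target genes and the inhibitory receptor and exhaustion genes were each called lower than other genes, through a minority of members. Neither call held with an estimated correlation. Of 36 measured IL-2 and STAT5 targets, 9 rose, 10 fell and 17 did not pass (9 and 11 adjusted over the list alone), and 6 rose and 16 fell after median ratio scaling. Dusp5 fell from 176 ± 19.1 to 22.6 ± 3.25 TPM, Gadd45b from 242 ± 17.4 to 60.5 ± 4.60 TPM and the kinase gene Pim1 from 694 ± 76.6 to 233 ± 16.4 TPM. The median was 0.02 but the mean -0.19, and the set test pointed down (adjusted p = 0.0103, but adjusted p = 0.631 with an estimated correlation). It missed the threshold after median ratio scaling (adjusted p = 0.0547) and quantile scaling (0.110). The list's change relative to other genes was -0.305 and -0.268 there, against -0.298 with TPM as deposited.

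Of 25 measured inhibitory receptor and exhaustion genes, 8 rose, 9 fell and 8 did not pass, with the same counts adjusted over the list alone (8 and 9), and 6 rose and 10 fell after median ratio scaling. Ctla4, a receptor that blocks costimulation, fell 9.92-fold from 55.9 ± 4.72 to 5.64 ± 1.31 TPM. The nuclear receptor genes Nr4a1 (251 ± 74.8 to 29.4 ± 0.775 TPM) and Nr4a3 (20.3 ± 1.56 to 7.70 ± 0.907 TPM) fell, and 4 of the 9 that fell were also in the activation list. Pdcd1, which encodes PD-1, rose from 2.33 ± 0.556 to 4.92 ± 1.71 TPM and Lag3 from 19.1 ± 4.95 to 30.3 ± 6.11 TPM. Without Rig1 KO 3 or Rig1 KO 4 the number that rose was 4, and without Rig1 KO 2 it was 5. The median was 0.03 but the mean -0.44, and the set test pointed down (adjusted p = 0.0112, but adjusted p = 0.667 with an estimated correlation and 0.0943 after median ratio scaling). The list's change relative to other genes was -0.538 after that scaling, against -0.545 with TPM as deposited.

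Neither the proliferation nor the apoptosis genes were called as a list. Of 42 measured proliferation genes, 10 rose, 4 fell (Pcna, Cenpa, Cdt1 and Ccne2) and 28 did not pass (9 and 4 adjusted over the list alone). Pcna, the sliding clamp of DNA replication, fell from 421 ± 17.2 to 239 ± 19.9 TPM and the cyclin gene Ccne1 rose from 14.1 ± 1.92 to 32.2 ± 4.17 TPM. The number that rose was 7 after median ratio scaling, against 7 that fell, and it hung on single libraries, with 21 rising without WT 4, 6 without WT 2, 4 without Rig1 KO 3 and 5 without Rig1 KO 4. Of 29 apoptosis genes, 12 rose, 5 fell (Tnfrsf10b, Cdkn1a, Birc2, Pmaip1 and Birc3) and 12 did not pass (12 and 5 adjusted over the list alone), but 6 rose and 8 fell after median ratio scaling. Fasl, the death ligand of cytotoxic cells, rose from 8.86 ± 1.95 to 23.2 ± 3.93 TPM. The set tests gave adjusted p = 0.802 for proliferation (median 0.33) and 0.628 for apoptosis, where the median was 0.17 but the test pointed down. The apoptosis median was 0.095 without WT 2 and 0.068 without Rig1 KO 3 (28 measured).

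Some chaperone genes fell in Rig1 KO. Of 26 measured, 7 fell, 0 rose and 19 did not pass (7 and 0 adjusted over the list alone), while 13 fell and 0 rose after median ratio scaling. Hspa5, the main chaperone of the endoplasmic reticulum, fell 1.99-fold from 1653 ± 61.2 to 829.7 ± 99.5 TPM, and the cochaperone gene Dnajb4 fell 2.92-fold from 26.9 ± 2.71 to 9.20 ± 0.237 TPM. The heat-inducible Hspa1b, which shares most of its sequence with Hspa1a, fell from 87.6 ± 45.7 to 26.7 ± 6.26 TPM. The median was -0.16 and the set test gave an adjusted p of 0.000338, but adjusted p = 0.631 with an estimated correlation. With the B cell marker mean as a covariate the adjusted p was 0.124, with 2 members rising and 3 falling.

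Of 72 measured ribosomal protein genes, 14 fell, 0 rose and 58 did not pass, and adjusted over the list alone 0 rose and 0 fell. Rps9 fell from 4346 ± 204 to 3552 ± 402 TPM and Rps13 from 1626 ± 113 to 1264 ± 186 TPM. The median was -0.22 and the set test gave an adjusted p of 9.44e-10, but adjusted p = 0.631 with an estimated correlation, and after quantile scaling 6 rose and 2 fell. The number that fell was 2 without WT 2 or without Rig1 KO 3, 3 without Rig1 KO 4, 4 without WT 1, 5 without WT 3 and 9 without WT 5, and it was 28 without Rig1 KO 1 and 32 without Rig1 KO 2. Of 72 oxidative phosphorylation genes, 11 rose, 12 fell and 49 did not pass (10 and 11 adjusted over the list alone), and 6 rose and 20 fell after median ratio scaling. Ndufv2 rose from 25.5 ± 2.37 to 40.5 ± 4.34 TPM and Ndufs4, of the same complex, fell from 5.97 ± 0.243 to 3.77 ± 0.272 TPM. The median was 0.01 and the mean -0.03, and the set test pointed down (adjusted p = 0.0284, but adjusted p = 0.631 with an estimated correlation, 0.285 without Rig1 KO 3 and 0.152 without Rig1 KO 4).

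Of 21 glycolysis genes, 5 rose (Pfkp, Pgk1, Hk1, Eno1 and Slc2a3), 2 fell (Slc2a1 and Ldhb) and 14 did not pass, 4 and 2 adjusted over the list alone, while 1 rose and 4 fell after median ratio scaling. The glucose transporter gene Slc2a1 fell 2.93-fold from 35.9 ± 1.70 to 12.3 ± 1.39 TPM. The number that rose was 2 without Rig1 KO 3 and 3 without WT 1, WT 2, WT 3, Rig1 KO 1 or Rig1 KO 4. Of 31 proteasome genes, 7 rose, 3 fell (Psmb6, Psmb2 and Psmc6) and 21 did not pass (6 and 3 adjusted over the list alone), but 0 rose and 12 fell after median ratio scaling, and 4 rather than 7 rose without WT 1. The set tests pointed down for both, with adjusted p = 0.602 for glycolysis (median 0.10, mean -0.01) and 0.436 for the proteasome (median 0.06). An exact permutation test of the list means, less the mean of all tested genes, placed the libraries of the 2 genotypes apart for glycolysis (adjusted p = 0.0220).

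Transcripts of other cell types differed between the genotypes. B cell markers were lower in Rig1 KO, with 12 of 13 measured falling, 0 rising and Cd22 not passing (12 and 0 adjusted over the list alone). Cd79a, a chain of the B cell receptor, fell from 165 ± 135 to 19.6 ± 10.5 TPM. The mean log2(TPM + 1) of the B cell markers was 4.76 ± 0.969 in WT and 2.70 ± 0.608 in Rig1 KO, so the WT libraries were both higher and more spread. The median log2 fold change was -2.32 and the set test gave an adjusted p of 2.03e-07, but adjusted p = 0.631 with an estimated correlation. Of 12 dendritic cell markers, 4 fell, 1 rose and 7 did not pass (4 and 1 adjusted over the list alone). The 4 were the MHC class II genes H2-Eb1 (224 ± 167 to 35.9 ± 12.4 TPM), H2-Ab1 and H2-Aa and their chaperone gene Cd74, all of which B cells also express, and Itgax rose from 18.8 ± 10.7 to 55.5 ± 5.66 TPM. The median was -0.54 (adjusted p = 0.00620, but adjusted p = 0.631 with an estimated correlation, 0.0843 after median ratio scaling and 0.967 with the B cell marker mean as a covariate). Their median was -0.30 without WT 5 and -0.06 without WT 4 and WT 5.

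Platelet and megakaryocyte markers were lower in every Rig1 KO library. Of 11 measured, 10 fell, 0 rose and Clec1b did not pass (10 and 0 adjusted over the list alone). Ppbp, a platelet chemokine, fell from 103 ± 14.0 to 15.9 ± 4.24 TPM and Pf4, platelet factor 4, from 77.0 ± 9.48 to 7.41 ± 3.21 TPM. The mean log2(TPM + 1) of the markers was 3.95 ± 0.124 in WT and 2.32 ± 0.0610 in Rig1 KO, and the set test gave an adjusted p of 2.38e-10 (0.0134 with an estimated correlation), with a median of -1.50. Of 12 stromal and endothelial markers, 9 fell, 0 rose and 3 did not pass (9 and 0 adjusted over the list alone), all but Pecam1 below 10 TPM in either group, such as Sparc, which fell from 3.58 ± 1.49 to 0.688 ± 0.248 TPM. Their median was -0.66 (adjusted p = 2.68e-05, but adjusted p = 0.384 with an estimated correlation). Without WT 2 or without WT 4 only 9 members passed the filter, and 5 of these fell, against 9 of 12 with all libraries. The median of the members then measured was -0.42 without WT 2, -0.34 without WT 4 and, again over 9 members, -0.43 without WT 5. The platelet and stromal markers fell with the activation genes, and the libraries of each genotype lay apart for all 3 lists.

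**Figure D4:**
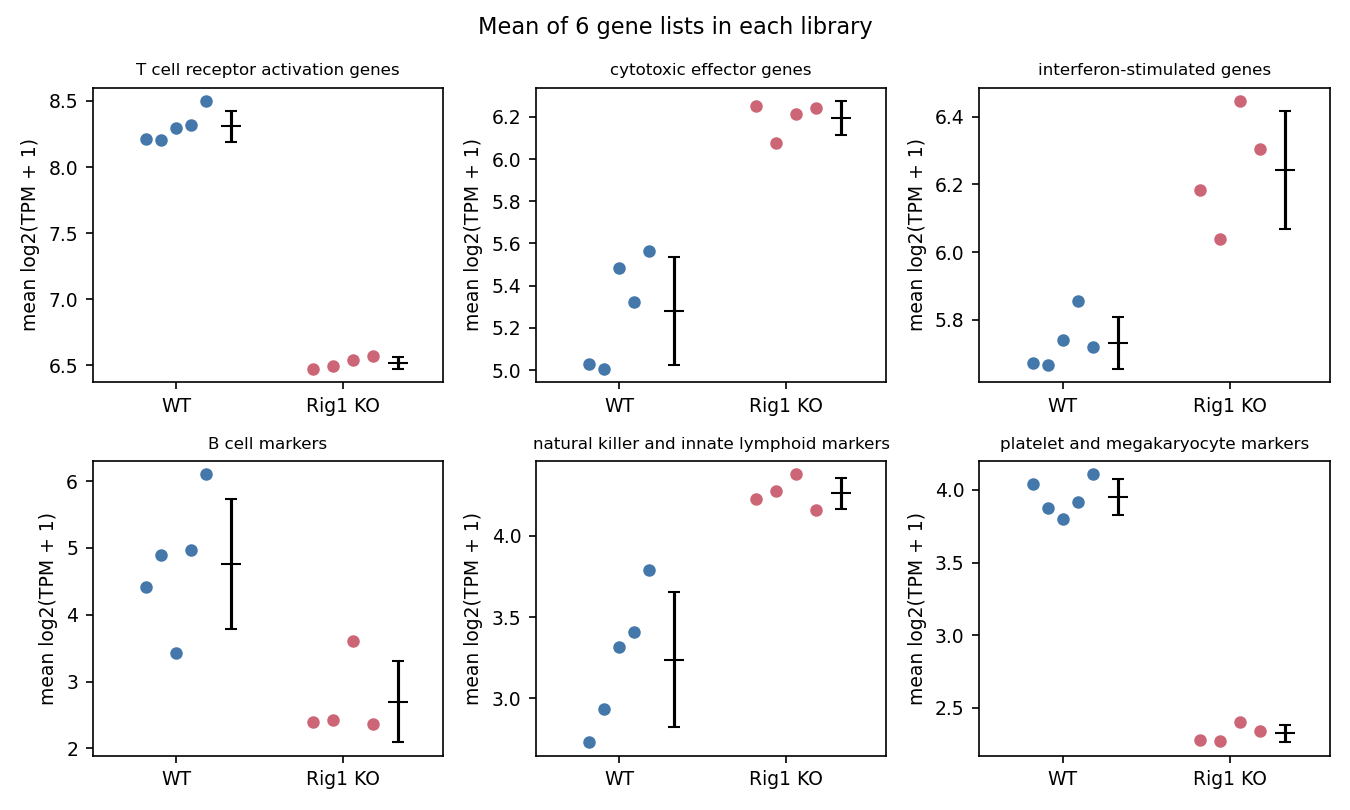
Mean log2(TPM + 1) of the members of 6 gene lists in each library (points, WT n = 5 and Rig1 KO n = 4) with the group mean and SD. The activation list lay at 8.31 ± 0.119 in WT and 6.52 ± 0.0441 in Rig1 KO and the platelet list at 3.95 ± 0.124 and 2.32 ± 0.0610, while the B cell list overlapped between the groups.

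Of 6 measured plasma cell markers, 2 rose, 1 fell and 3 did not pass (2 and 2 adjusted over the list alone, and 2 and 2 after median ratio scaling). Jchain, which joins secreted antibodies, rose from 62.8 ± 26.0 to 150.3 ± 19.1 TPM and Txndc5 rose too, while Irf4, which is also an activation gene of T cells, fell from 58.4 ± 14.6 to 12.4 ± 2.34 TPM. The median was 0.29 and the mean 0.02, whereas the test pointed down (adjusted p = 0.628). Of 11 CD4 T cell markers, 2 rose, 3 fell (Ctla4, Ikzf2 and Cd40lg) and 6 did not pass (2 and 3 adjusted over the list alone), and 2 rose and 5 fell after median ratio scaling. Cd4 itself was at 13.0 ± 12.3 TPM in WT and 4.38 ± 0.879 TPM in Rig1 KO and did not pass. Their median was -0.02 (adjusted p = 0.0632, 0.0372 without WT 1 and 0.0468 without Rig1 KO 1). The set test of the CD4 markers gave an adjusted p of 0.631 with an estimated correlation, and limma's fry gave 0.0317. Of 21 macrophage and monocyte markers, 6 rose, 0 fell and 15 did not pass (5 and 0 adjusted over the list alone), led by Ccr2, with Vcam1 rising from 89.8 ± 31.3 to 159 ± 22.4 TPM. Their median was 0.40 (adjusted p = 0.323) and 0.22 without WT 1, and 3 rather than 6 rose without Rig1 KO 3. Without WT 4 and WT 5, 15 rose and the adjusted p was 0.0282.

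A knockout can carry flanking DNA of another strain, which would show as changed genes around the target. Of 100 tested genes within 10 Mb of the RIG-I gene, 54 changed (54.0%), against 4724 of 10332 elsewhere (45.7%). The odds ratio was 1.39 (95% interval 0.921 to 2.12, Fisher's exact p = 0.107), so no excess was shown. The test of changed genes near Rigi (the current symbol of Ddx58) depended on single libraries, with an odds ratio of 1.54 (Fisher's exact p = 0.0395) without WT 2, 1.51 (Fisher's exact p = 0.0439) without WT 5 and 1.55 (Fisher's exact p = 0.0362) without Rig1 KO 4.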

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

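The patterns of gene groups were chosen after they were seen, and what each explanation would predict was written before its test was run, except for handling and for a shared rise of all other cells, which were chosen only after the result was seen.

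The fall of the activation genes in Rig1 KO, by a mean log2 fold change of -1.79, was weighed against technical explanations. With the B cell marker mean as a covariate the genotype term was -1.65 (SE 0.0947). The larger share of B cell transcripts in WT therefore does not account for the fall alone. That marker mean also differed with genotype (4.76 ± 0.969 in WT and 2.70 ± 0.608 in Rig1 KO), although the groups overlapped. Nor does the scaling of the libraries account for the fall, since the weakest value under 3 other scalings was -1.76. Handling that differed between the genotypes was not tested, since no label gives the order or day of isolation. The gap of 1.64 log2 units between the lowest WT and the highest Rig1 KO library would follow from genotype and from handling alike, so it speaks for neither.

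The rise of the cytotoxic genes was weighed against other cells in the preparation. With the natural killer marker mean as a covariate the genotype term of the list fell from 0.91 to 0.37 (SE 0.155), but that marker mean was itself tied to genotype (r = 0.874), so the part that natural killer cells contribute cannot be separated. Natural killer and platelet markers moved apart by 2.65 on the log2 scale. A lower share of B cells that raises all other cells alike would not move them apart. The test was chosen after these directions were seen, and a separate loss of platelets would give the same gap. The gap therefore does not show whether a lower share of B cells contributed to the rise of the cytotoxic genes. More effector-type CD8+ T cells may also explain the rise, since 8 of the 14 natural killer markers are known from CD8+ T cells, and this was not tested.

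Mcpt8 and Prss34, the 2 named genes with the largest rise on the log2(TPM + 1) scale (11.01-fold and 8.96-fold by the ratio of means, against 11.9-fold for Gzmk), are known from basophils, which may have been more frequent in the Rig1 KO libraries. Of 7 other tested basophil markers, 5 rose (Fcer1a, Cpa3, Gata2, Cd200r3 and Cyp11a1), Il4 did not pass (adjusted p = 0.0668) and Hdc fell from 5.58 ± 0.913 to 3.30 ± 0.449 TPM. Gata2, 1 of the 5, went from 7.64 ± 3.52 to 15.9 ± 1.78 TPM. The fall of Hdc goes against more basophils and the 5 rises go with them, so the source of the 2 transcripts stays open. 1 of the 9 basophil markers is also known from CD8+ T cells.

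Chance is an unlikely source of the count of changed genes, since 1 of 100 splits of the 9 libraries into 5 and 4 (the real one) gave as many as 4817. The highest other gave 2013, in a split that kept all Rig1 KO libraries together in the group of 5. For the count of called lists, 24 of 100 splits gave at least the 13 of the real one and the highest other gave 16. The splits cannot decide on this count, since many divide the Rig1 KO libraries unevenly and so keep part of the genotype difference. The splits with 16 lists had 1 Rig1 KO library in the group of 4. Chance was thus neither excluded nor shown for the list count.

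Single libraries stood apart from their group in 7 of 98 values examined, where chance gives about 5 percent. Rig1 KO 2 held 291.7 TPM of Prss34, against 149.7 to 159.0 in the other Rig1 KO libraries. WT 5 held 22.1 TPM of H2-Q10, against 14.3 to 15.01 in the other WT libraries. Cxcl2 was at 1.51 TPM in Rig1 KO 3 and at 0.302 to 0.371 in the others. Plk2 was at 3.98 TPM in Rig1 KO 1 and at 2.38 to 2.55 in the others. The B cell marker mean was 3.61 in Rig1 KO 3 and 2.37 to 2.43 in the others. WT 2 had 15196 genes above 0, against 15517 to 15631, and Rig1 KO 1 had 15511, against 15464 to 15471.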

How the results depend on the processing

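Voom, recovered reads scaled to equal totals, exon lengths, the length and GC trend, the B cell covariate, the data without WT 4 and WT 5 and the exact permutation test of the lists were chosen only after the result was seen. Ddx58 stayed lower under every alternative run. The count of genes changed between Rig1 KO and WT stayed within 1.5 times of 4817 except with the B cell marker mean as a covariate (2765 changed, 2179 higher and 586 lower) and at an absolute log2 fold change of at least 1 (539 changed, 250 higher and 289 lower); the covariate's loss may include calls carried by B cell transcripts, and its cause was not tested. The count of lower genes moved from 1291 to 2384 with median ratio scaling, 2195 with quantile scaling, 2494 with voom and 2128 with recovered reads scaled to equal totals, which centre the genes differently. Leaving out 1 library gave 3993 to 4788 changed genes, and removing the length and GC trend gave 5107. Of the lists, 13 were called, 2 of them with an estimated correlation (activation and platelet), and 9 were called with quantile scaling. The exact permutation test called 12 lists, adding glycolysis and CD4 T cell markers and losing ribosomal protein, oxidative phosphorylation and dendritic genes (adjusted p = 0.105, 0.258 and 0.0794). The odds ratio near the RIG-I gene was 1.27 to 1.55 with single libraries left out.

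Of the list values under the alternatives, 637 kept direction and call, 34 lost the call, 16 gained it and 12 changed sign, in lists that were mostly near 0 relative to other genes. The apoptosis list (-0.02) became 0.0269 with no filter, 0.00062 with the replicate block, 0.0106 with exon lengths and 0.0405 with the B cell covariate. The plasma cell list (-0.09) became 0.0421 with the block, 0.37 with the B cell covariate, 0.0759 without WT 4 and WT 5, 0.0390 without WT 5 and -0.16 without WT 1. With the B cell covariate the T cell receptor complex list became -0.0238, the neutrophil list 0.81 and the dendritic list 0.34, and without WT 4 and WT 5 the neutrophil list became 0.15. The cause was not tested. Of the named genes' values, 2838 kept direction and call, 51 lost the call and 0 changed sign. The replicate numbers of the titles do not pair the libraries, since same-numbered libraries correlated at 0.0972, -0.0601, -0.0996 and -0.0724 and only Rig1 KO 1 correlated best with its own number. The column headers number the Rig1 KO libraries 2 to 5, by which only Rig1 KO 3 correlated best with its own number, and this numbering was not used as a block. With the number as a block 4777 genes changed and 13 lists were called. Only WT has a number 5, so the block estimates each gene's change without WT 5. The log2 fold change of Ddx58 was -0.959 in both fits, and the block is no separate check of direction. Depth limits the lowest genes, such as Cxcl2 with 7 reads in Rig1 KO.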

Other observations

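No test in this part was planned beyond the gene lists, and the comparison of gene lengths was chosen only after the values were seen. Neutrophil markers moved in both directions. Ctsg rose from 12.6 ± 8.05 to 55.1 ± 10.4 TPM, Mpo from 17.0 ± 10.5 to 55.1 ± 9.78 TPM, and Prtn3 and Elane rose with them, all enzymes of the primary granules. Il1b, an inflammatory cytokine that monocytes also make, fell from 28.7 ± 10.4 to 3.51 ± 0.270 TPM, and the calcium-binding genes S100a8 and S100a9 fell. Of 17 measured markers, 4 rose, 3 fell and 10 did not pass (4 and 3 adjusted over the list alone), with a median of -0.59 and an adjusted p of 0.0532, which became 0.0436 without WT 1, 0.000833 without WT 3, 0.0261 without Rig1 KO 2 and 0.0332 with totals free of immunoglobulin, haemoglobin and mitochondrial genes. It was 0.780 with an estimated correlation and 0.616 with fry, and the median was -0.25 without WT 5 and 0.05 without WT 4 and WT 5. The number that fell was 10 without WT 3 and 1 without Rig1 KO 4, and with the B cell marker mean as a covariate 7 rose and 1 fell.

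The call of the erythroid markers as a list depended on the libraries. Of 13 measured, 6 rose, 1 fell and 6 did not pass (6 and 1 adjusted over the list alone), and 4 rose and 1 fell after median ratio scaling. The globin gene Hbb-bs rose from 34.9 ± 19.2 to 101 ± 24.5 TPM and Car1, a carbonic anhydrase of red cells, from 3.30 ± 1.72 to 7.39 ± 1.35 TPM, while the transferrin receptor gene Tfrc, which activated T cells also express, fell from 61.2 ± 4.72 to 38.0 ± 4.82 TPM. The median was 0.73 and the adjusted p 0.342, and 10 rather than 6 rose without WT 4. Without WT 4 and WT 5, 11 rose and the list was called (adjusted p = 0.0356). With all libraries and an estimated correlation the set test gave an adjusted p of 0.849. The globin genes have near-identical copies, so their single values are uncertain. Of the gamma-delta T cell markers 3 were measured. Maf rose from 10.7 ± 3.03 to 18.6 ± 2.75 TPM, Il17a fell from 3.86 ± 3.25 to 0.342 ± 0.0931 TPM, and Blk, which B cells also express, fell.

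The Y-linked gene Ddx3y was at 82.9 to 127 TPM in all 9 libraries, so each library held male cells. Kdm5d and Uty rose and Eif2s3y fell, with no shared direction.

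The lengths behind the TPM values followed the genomic span of each gene (Spearman rho of 0.993 across genes, which are not independent replicates) more closely than its exon length (0.618). For Ddx58 the implied length was 36056 bases, equal to its span, against 7050 bases of exons. With TPM rebuilt from exon lengths, 5139 of 11484 genes changed, 66.2% of them higher in Rig1 KO.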
